A study of Mus musculus with 14 samples.

How the data were processed

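The sources used here are the deposited tables, the labels and the series description. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was isolated on Dynabeads, and libraries were made by DP-seq, which copies transcripts from a set of designed primers. CASAVA 1.8 is the tool recorded in the submitters' processing notes. The deposited values are counts of unique reads per RefSeq transcript, per the file headers, and every value is a whole number of 0 or more. The aligner, the RefSeq release, the genome build and the treatment of reads shared between transcripts or genes are not given in the sources used here. Transcripts of 1 gene, paralogs and pseudogenes may therefore split reads in an unknown way, and strand is not given.

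Each of the 14 tables lists the same 26566 transcripts, 24896 coding and 1670 noncoding. Symbols came from a RefSeq gene table of assembly GRCm38.p6, used for names and neighbours alone, in which 25857 transcripts found a symbol and 709 did not. The unnamed took 0.545% to 1.46% of the counts of a library. There were 21174 symbols, 3052 of them with more than 1 transcript, and the transcript with the highest mean CPM stands for its gene.

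Groups follow the titles. Neuron and Astrocyte are untransduced. The title ENSC stands beside a source and cell type of embryonic stem cells, so the group is called by its title. The labels name DMEM for a group of transduced neurons although their growth protocol gives Neurobasal-A for neurons, and the title was followed. Replicate numbers repeat across groups without a stated link.

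CPM are counts scaled by library total and TMM factor in edgeR. Transcripts with at least 10 counts in at least 2 libraries were tested, 13132 in all. The edgeR quasi-likelihood test with robust estimation was fitted once to all 14 libraries and 8 groups, so that every comparison shares 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. ESC and Tumour have 1 library each and are assumed to vary like the replicated groups. The difference between the changes of neurons and astrocytes is an interaction term of the same fit. Log2 changes are the coefficients that edgeR gives, standard errors come from these and the F statistic, and log2 CPM uses a prior count of 2. Where a group has no counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio of pooled counts with an exact 95% interval.

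The 24 gene lists were neuronal structure, synapse, astrocyte, neural stem and progenitor, pluripotency, S phase, G2 and M phase, RAS-MAPK output, p53 targets, NF-kB targets, mesenchymal glioma, proneural glioma, matrix and adhesion, meningeal fibroblast and mural, microglia and macrophage, oligodendrocyte lineage, endothelial and blood, interferon response, glycolysis and hypoxia, oxidative phosphorylation, sterol synthesis, cytosolic ribosomal proteins, unfolded protein and amino acid stress, and immediate early genes. They were written from general knowledge before the data were examined. Each was tested in the 13 comparisons with camera of limma at a preset correlation of 0.01 between genes, and adjusted over all 312 tests. Of these, 167 passed. Camera with the correlation estimated from the data and the fry test were run beside it.

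Position is the projection of a library onto the line between mean log2 CPM of the starting cells and of ENSC. Agreement between comparisons is the Pearson correlation of log2 changes, set beside simulated groups without any change where both use the same libraries.

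The comparisons, tests, lists and most alternatives were fixed before the data were examined, as was the rule for genes named. Hras and Trp53 were always included. The rule then took transcripts that passed, had a mean of at least 20 CPM in the higher group and did not overlap between groups. Of these it allowed the 8 largest in each direction for the comparisons of NSC medium against Neuron and against DMEM and for astrocytes, and the 4 largest elsewhere. Names of predicted genes, unnamed transcripts, haemoglobins, major urinary proteins and histones were skipped. For each list it allowed up to 4 passing members of largest change, or the 2 most abundant where none passed. Igfbp3, genes described again in a comparison where the rule did not name them, and the further genes of the closing section were chosen after their values were seen.

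Alternatives were DESeq2 size factors, the DESeq2 Wald test, limma voom, no filter on low counts, at least 50 counts, the compared groups alone, each replicate left out, a replicate block, and other prior counts. Sums by symbol came later. With DESeq2 size factors the median log2 change of all transcripts tested moved from -0.003 to -0.105 for transduced neurons in DMEM against Neuron, from 0.014 to -0.085 in NSC medium, and from 0.047 to -0.096 for ENSC against Neuron, and changes are read relative to it.

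The steps were tried on simulated counts with the means and spread of these libraries, for transduced neurons in NSC medium against Neuron with 13131 transcripts tested. Of 50 transcripts changed at each size, edgeR recovered 1 at 2-fold, 25 at 4-fold, 47 at 8-fold and 47 at 16-fold, and in the difference of changes 1, 5, 31 and 41. In the former 11 unchanged transcripts were called, 8.40% of the calls. The moved list was called and 0 of 22 others were, with independent genes, so effects of correlation were untested. Positions set at 0, 0.5 and 1 came out at 0.0035, 0.56 and 1.001. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.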

Results

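The series measured poly(A) RNA of C57BL/6 mouse cells by DP-seq, a designed-primer form of RNA sequencing, as whole read counts of 26566 RefSeq transcripts in 14 libraries. The libraries fall into 8 groups. Cultured cortical neurons and cortical astrocytes of postnatal day 11 mice gave 2 libraries each. Neurons carrying a lentivirus with activated HRas and a hairpin against p53 gave 2 libraries after DMEM and 2 after NSC medium, a serum-free medium with FGF-2. Astrocytes with the same virus in NSC medium gave 2 libraries. A tumour raised by this virus in the cortex of a SynapsinI-Cre mouse gave 1 library. The group titled ENSC gave 2 libraries and the group titled ESC gave 1. The stated purpose of the series was to ask whether transduced brain cells move toward an undifferentiated state. Whether replicates came from separate cultures or animals is not given in the sources used here, so every p-value measures only the spread between these libraries.

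Total counts ran from 7731378 in the tumour to 14608940 in replicate 2 of transduced neurons in DMEM, and 13802 to 15964 transcripts had at least 1 count. Across genes, which are not independent replicates, replicate pairs correlated with r = 0.926 in Neuron, 0.940 in transduced neurons in DMEM and 0.954 in NSC medium. In Astrocyte r was 0.981, in transduced astrocytes 0.976 and in ENSC 0.986. The biological coefficient of variation was 32.8%, and the largest principal components took 28.8%, 18.9% and 14.7% of the variance. Values written a ± b are edgeR log2 changes with standard errors. Where a group had 3 counts or fewer a ratio of pooled counts is given instead, as "at least n-fold" if the group had 0. Intervals and the 3-count floor behind "at least" cover counting error only, and "with bounds" marks a median in which members at 0 stand at that floor. Every single gene said to rise or fall had an adjusted p under 0.05 in edgeR. Statements on a class of genes speak of its list as a whole, not of each member. They rest on a test at a preset correlation between genes, and with an estimated correlation no list passed in any comparison.

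The virus carries HRas and a hairpin against p53, so both genes come first. Hras had at most 2 counts in any library, with or without virus. Why was not tested. Whether these counts could register the HRas of the virus is not given in the sources used here, so they do not show which libraries carry it. Trp53, summed over its transcripts, had 73 and 26 counts in Neuron, 14 and 8 in transduced neurons in DMEM, and 32 and 13 in NSC medium. It had 77 and 69 counts in Astrocyte, 21 and 24 in transduced astrocytes and 3 in the tumour. For its most abundant transcript alone the change from Neuron was -1.87 ± 0.63 (adjusted p = 0.0535) in DMEM and -0.57 ± 0.58 (adjusted p = 0.532) in NSC medium, and in transduced astrocytes it was -1.12 ± 0.58 (adjusted p = 0.159). None of these passed. With counts summed by symbol they were -2.21 (adjusted p = 0.0323), -1.12 (adjusted p = 0.228) and -1.46 (adjusted p = 0.0855), so the fall in DMEM passed only there. Without Neuron replicate 1 the single-transcript value in NSC medium turned to 0.35. The tumour was lower in Trp53 (11.9-fold, 95% interval 3.15 to 100.02, adjusted p = 0.0424) than Neuron.

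**Figure D1:**
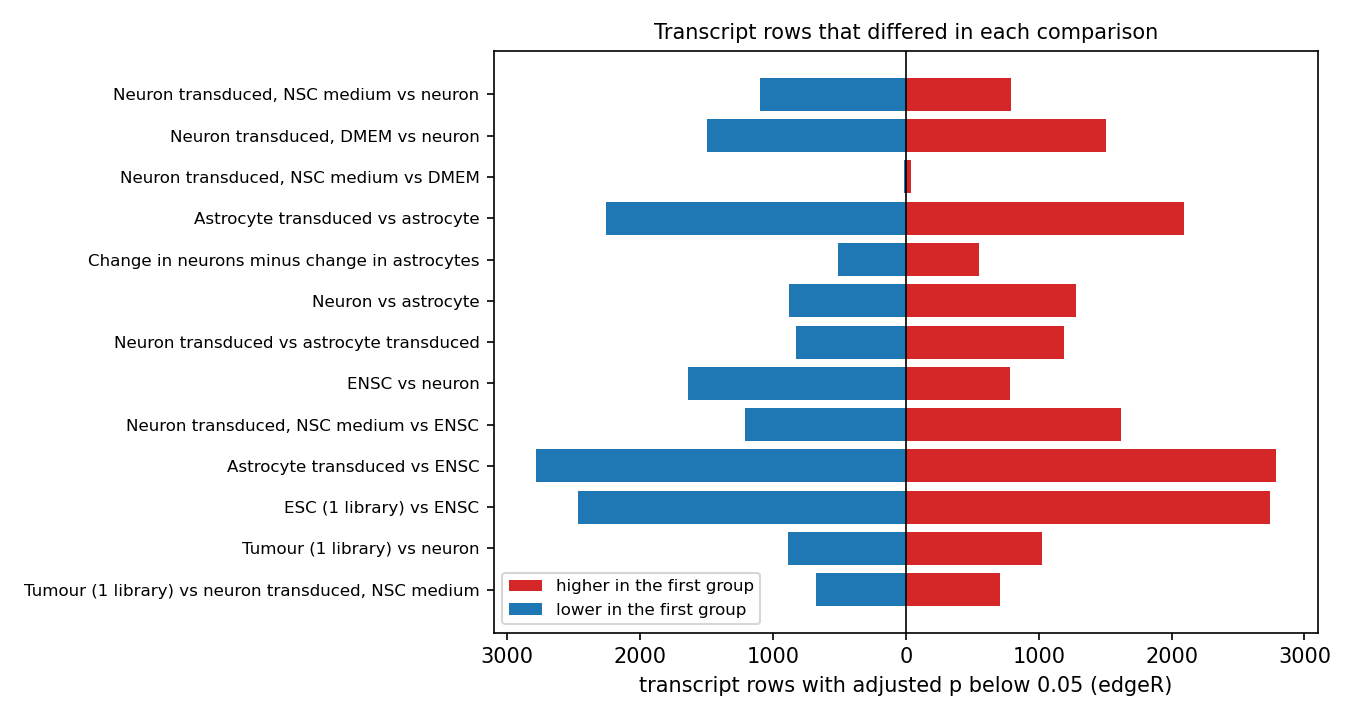
Number of transcripts higher and lower in each comparison at an adjusted p under 0.05 by edgeR, of 13132 tested. Transduced neurons in NSC medium and in DMEM differed in 52 transcripts, and transduced astrocytes differed from astrocytes in 4350.

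Transduced neurons in NSC medium were compared with untransduced neurons to see what the virus and the new medium changed together. The list of RAS-MAPK output genes moved up, and the synapse list down. The tumour suppressor Cdkn2a (7.39 ± 0.45, adjusted p = 9.77e-05), known to respond to RAS, stood at 1.48 and 0.76 CPM in Neuron and at 188 and 187 CPM in the transduced cells. In edgeR, 1889 of 13132 transcripts tested changed, 794 higher and 1095 lower. Among 23 RAS-MAPK output genes, 14 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 change of 2.36, adjusted p = 5.59e-11 (adjusted p = 0.345 with an estimated correlation). They included the EGF-receptor ligands Areg (101-fold, 95% interval 34.1 to 491, adjusted p = 0.00706) and Ereg (5.33 ± 0.92, adjusted p = 0.00745), the AP-1 gene Fosl1 (75.5-fold, 95% interval 13.1 to 3023) and the chromatin gene Hmga2 (5.85 ± 1.06). Other large rises were Calcb (at least 259-fold, adjusted p = 0.0348), Btn1a1 (7.61 ± 1.02), Nptx1 (6.91 ± 0.64), Ppl (6.54 ± 1.22), Tcam1 (6.48 ± 0.79), Esm1 (6.46 ± 0.92) and the BMP antagonist Grem1 (5.94 ± 1.21). Igfbp3, which encodes an IGF-binding protein, stood at 3788 and 180.1 CPM in the Neuron replicates, far apart, and at 29881 and 18728 CPM in the transduced cells, their most abundant transcript.

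Among 23 synapse genes, 14 fell (16 adjusted over the list alone), with a median log2 change of -3.27, adjusted p = 6.23e-09 (adjusted p = 0.409 with an estimated correlation). The vesicular transporters Slc32a1 (at least 96.5-fold, adjusted p = 0.01) and Slc17a6 (493-fold, 95% interval 136 to 4076, adjusted p = 0.00446) fell, and so did Cplx1 (-8.04 ± 1.15) and Camk2a (178-fold, 95% interval 49.0 to 1476). Among 14 neuronal structure genes, 1 rose and 5 fell (2 and 8 adjusted over the list alone), with a median log2 change of -2.03, adjusted p = 0.0463 (adjusted p = 0.686 with an estimated correlation). L1cam, Ina and Tubb3 fell, Ina (-3.92 ± 0.75, adjusted p = 0.0101) for example, while the neurofilament gene Nefm (4.83 ± 0.87, adjusted p = 0.00907) rose. Lgi1 (797-fold, 95% interval 220.2 to 6584), Nrsn1 (-8.97 ± 1.00), Elmod1 (at least 284-fold), Mpped1 (at least 292-fold) and Spock3 (at least 217-fold), all active in neurons, were among the largest falls.

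Markers of other cell types present in the untransduced cultures fell in the same comparison. Among 24 microglia and macrophage genes, 19 fell (21 adjusted over the list alone), with a median log2 change of -4.91 (-4.76 with bounds), adjusted p = 1.1e-14 (adjusted p = 0.346 with an estimated correlation). The complement genes C1qa (at least 31.8-fold, adjusted p = 0.00555) and C1qc (353-fold, 95% interval 63.0 to 13993, adjusted p = 0.00354) led them. Among 22 meningeal fibroblast and mural genes, 13 fell (18 adjusted over the list alone), with a median log2 change of -4.23 (-3.45 with bounds), adjusted p = 2.53e-09 (adjusted p = 0.346 with an estimated correlation). Collagen genes fell most there, Col3a1 (-8.82 ± 1.38) and Col1a1 (-8.22 ± 1.5). Among 21 oligodendrocyte lineage genes, 10 fell (1 and 13 adjusted over the list alone), with a median log2 change of -2.68, adjusted p = 4.93e-06 (adjusted p = 0.423 with an estimated correlation). The myelin genes Cldn11 (at least 61.5-fold) and Mag (at least 31.5-fold) fell. Among 21 astrocyte genes, 11 fell (11 adjusted over the list alone), with a median log2 change of -1.63, adjusted p = 7.24e-06 (adjusted p = 0.446 with an estimated correlation). Aqp4 (-4.55 ± 0.76) and Aldoc (-4.24 ± 0.77) were among these, and Ttr (-11.54 ± 2.14), known from choroid plexus, and Vtn (679.8-fold, 95% interval 122 to 26888) fell too.

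Progenitor genes moved in both directions. Among 31 neural stem and progenitor genes, 4 rose and 7 fell (8 and 9 adjusted over the list alone), with a median log2 change of -0.31, adjusted p = 0.636 (adjusted p = 0.946 with an estimated correlation). Nes rose, Nes (3.0 ± 0.57, adjusted p = 0.00993), and Sox1 (-2.55 ± 0.43) and Dll1 (-2.63 ± 0.57) fell. Among 12 pluripotency genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone), with a median log2 change of 0.01, adjusted p = 0.707 (adjusted p = 0.909 with an estimated correlation). Here the test pointed down while the median and mean were above 0. Among 32 G2 and M phase genes, 2 rose (0 adjusted over the list alone), with a median log2 change of 0.71, adjusted p = 0.00997 (adjusted p = 0.829 with an estimated correlation). Among 24 glycolysis and hypoxia genes, 5 rose (11 and 1 adjusted over the list alone), with a median log2 change of 1.15, adjusted p = 0.00168 (adjusted p = 0.613 with an estimated correlation). Aldoa (3.92 ± 1.12) and Slc2a3 (2.58 ± 0.71) were among the latter. Among 24 interferon response genes, 4 fell (7 adjusted over the list alone), with a median log2 change of -1.82, adjusted p = 0.000761 (adjusted p = 0.685 with an estimated correlation). Oas2 (45.9-fold, 95% interval 12.4 to 384) is an example. Among 28 p53 target genes, 3 rose (3 adjusted over the list alone), with a median log2 change of 0.54, adjusted p = 0.0105 (adjusted p = 0.675 with an estimated correlation). Among 27 oxidative phosphorylation genes edgeR passed 0, DESeq2 2 and limma 0, with 3 at an unadjusted p under 0.05 in edgeR and 0 passing adjusted over the list alone. The oxidative phosphorylation list had a median log2 change of -0.32, adjusted p = 0.261 (adjusted p = 0.877 with an estimated correlation).

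The number of changed transcripts depended on single libraries. It was 386 (210 higher and 176 lower) without replicate 1 and 799 without replicate 2 of the transduced neurons, 890 (241 and 649) without Neuron replicate 2, 352 (27.6% higher) with these 4 libraries alone and 3104 without the filter on low counts.

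**Figure D2:**
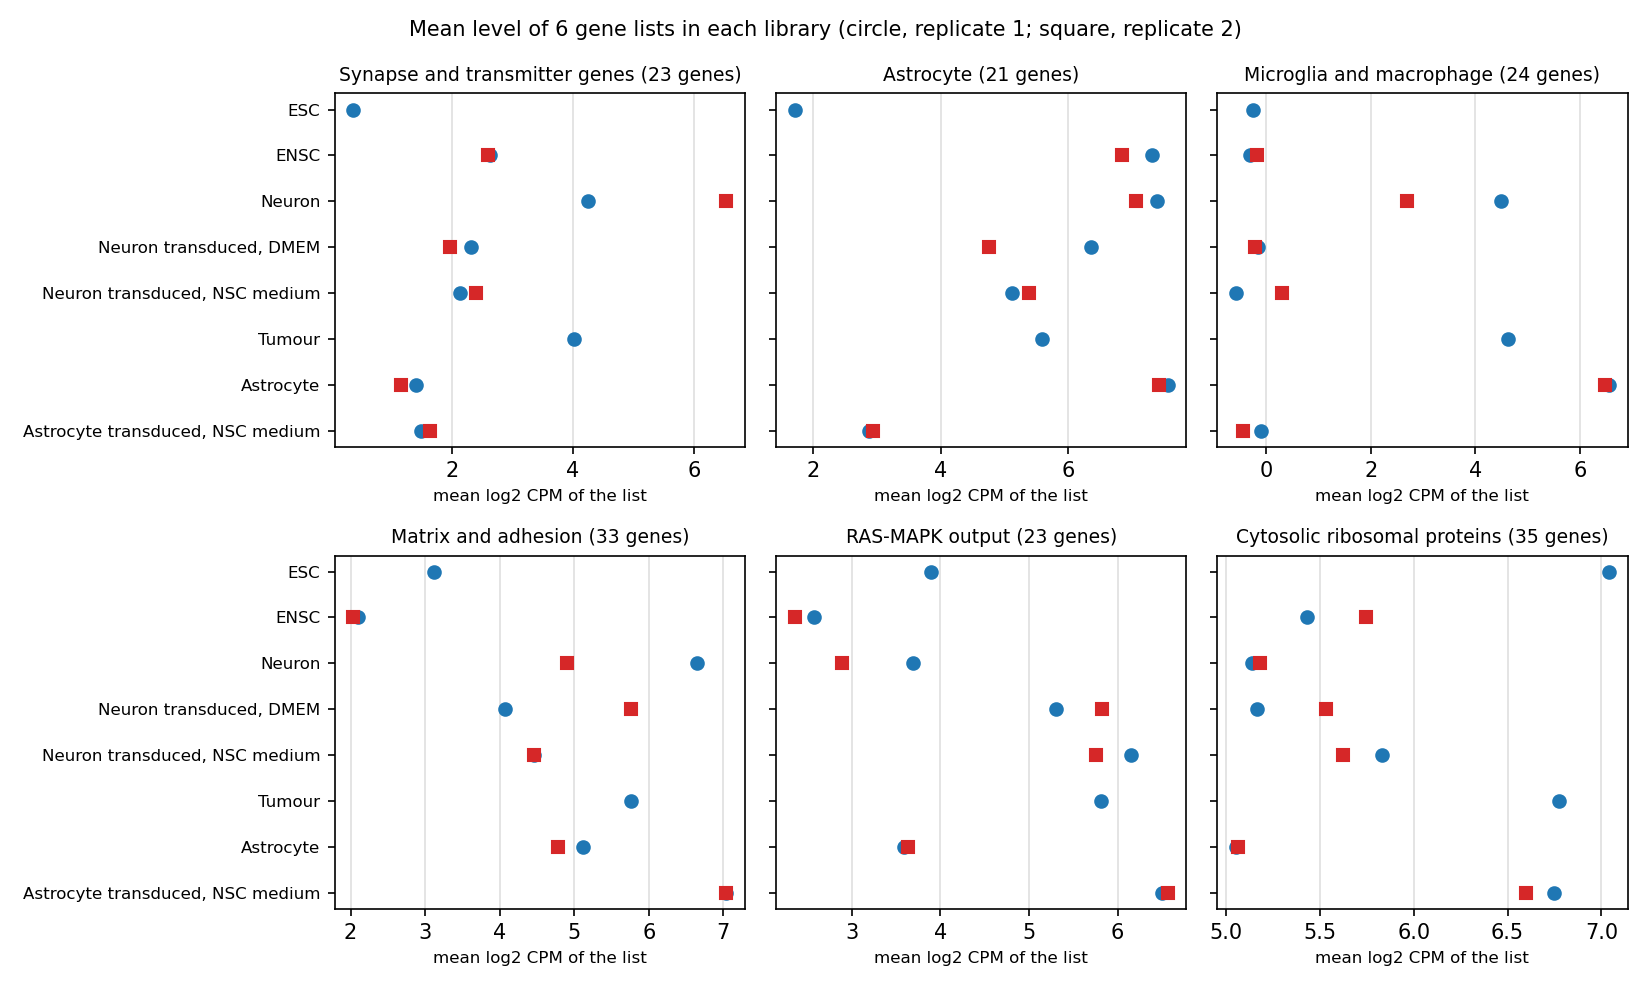
Mean log2 CPM of the members of 6 gene lists in each of the 14 libraries, circles for replicate 1 and squares for replicate 2. The microglia and macrophage list lies low in the transduced cultures and high in the tumour, where its median log2 difference from transduced neurons in NSC medium was 5.89.

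Transduced neurons in DMEM were compared with untransduced neurons. The cell-division lists moved up, mostly in replicate 2, beside the RAS-MAPK list, and the synapse list down. In edgeR, 3004 transcripts changed, 1507 higher and 1497 lower. Of the 23 RAS-MAPK output genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 change of 1.95, adjusted p = 4.07e-08 (adjusted p = 0.346 with an estimated correlation). Areg, Fosl1 and the feedback inhibitor Spry4 rose, Spry4 (4.55 ± 0.40, adjusted p = 0.000414) for example. Among 27 S-phase genes, 10 rose (14 adjusted over the list alone), with a median log2 change of 1.37, adjusted p = 6.43e-06 (adjusted p = 0.617 with an estimated correlation). E2f1 (2.87 ± 0.57) and the primase gene Prim1 (2.39 ± 0.60) were among them. Of the 32 G2 and M phase genes, 12 rose (14 adjusted over the list alone), with a median log2 change of 1.37, adjusted p = 8.26e-06 (adjusted p = 0.636 with an estimated correlation). Cdk1 (2.81 ± 0.66) and Kif2c (2.76 ± 0.76) rose. The largest rises were Cdkn2a (7.80 ± 0.46, adjusted p = 6.52e-05), Calcb (at least 464-fold, adjusted p = 0.0215), Btn1a1 (8.17 ± 1.05) and the neuropeptide gene Npvf (8.24 ± 1.8, adjusted p = 0.0122), the last at 389.9 and 10.1 CPM in its replicates. Among 22 NF-kB target genes, 6 rose (6 adjusted over the list alone), with a median log2 change of 0.92, adjusted p = 0.00625 (adjusted p = 0.613 with an estimated correlation). The cytokine genes Csf2 (at least 22.0-fold) and Ccl2 (4.54 ± 0.72) rose.

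Of the 23 synapse genes, 14 fell (15 adjusted over the list alone), with a median log2 change of -3.49, adjusted p = 7.29e-08 (adjusted p = 0.437 with an estimated correlation). Slc17a6 (1078-fold, 95% interval 193 to 42627, adjusted p = 0.00294) fell. Of the 24 microglia and macrophage genes, 21 fell (22 adjusted over the list alone), with a median log2 change of -5.26 (-4.78 with bounds), adjusted p = 6.08e-13 (adjusted p = 0.346 with an estimated correlation). Tyrobp (at least 57.5-fold) is an example. Of the 12 pluripotency genes, 4 fell (5 adjusted over the list alone), with a median log2 change of -1.53, adjusted p = 0.0221 (adjusted p = 0.399 with an estimated correlation). Lin28a (-2.73 ± 0.80) fell, from 26 and 27 counts to 2 and 6. Among 19 immediate early genes, 2 rose and 6 fell (3 and 7 adjusted over the list alone), with a median log2 change of -0.91, adjusted p = 0.0998 (adjusted p = 0.636 with an estimated correlation). Npas4 (-4.82 ± 0.50, adjusted p = 0.000957) and Nr4a1 (-3.42 ± 0.79) fell.

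Without replicate 2 of these transduced neurons 1083 transcripts changed, and without Neuron replicate 2 1277 did. With the 4 libraries alone edgeR called 0, with 2957 at an unadjusted p under 0.05.

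Transduced neurons in NSC medium were compared with those in DMEM. The edgeR count was low, but the DESeq2 test called many more. The interferon and NF-kB lists were lower in NSC medium at the preset correlation and not with an estimated one. In edgeR, 52 of 13132 transcripts tested differed, 37 higher and 15 lower, and 2443 had an unadjusted p under 0.05. The RNA-methylation gene Wtap (3.29 ± 0.27, adjusted p = 0.00162) was higher in NSC medium, at 169.7 and 138 CPM against 16.3 and 15.2 CPM. The ribosomal Rpl17 (3.07 ± 0.43, adjusted p = 0.0324), the cytoskeletal Actb (2.28 ± 0.37, adjusted p = 0.0424) and the EGF-family ligand Btc (2.28 ± 0.35, adjusted p = 0.0413) were higher too, with Poglut3 (2.47 ± 0.41), Slc39a10 (2.36 ± 0.34), Prkra (2.25 ± 0.32) and Rfxap (2.13 ± 0.28). Lower were the inflammatory caspase Casp4 (-4.56 ± 0.76, adjusted p = 0.0424), the glial potassium channel Kcnj10 (-4.15 ± 0.69, adjusted p = 0.0424), Hr (-3.32 ± 0.59), Lcat (-3.18 ± 0.54), Dhrs1 (-2.86 ± 0.41), Rexo1 (-2.82 ± 0.43), Lgals3bp (-2.81 ± 0.47) and Foxc1 (-2.79 ± 0.48). The sterol gene Cyp51 (1.85 ± 0.32) and the chaperone gene Dnajb9 (1.60 ± 0.27) were higher.

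Of the 24 interferon response genes edgeR passed 0, DESeq2 9 and limma 0, with 15 at an unadjusted p under 0.05 in edgeR and 14 passing adjusted over the list alone. The interferon response list had a median log2 difference of -2.38, adjusted p = 3.95e-09 (adjusted p = 0.452 with an estimated correlation). Its most abundant members, Isg15 (-4.53 ± 1.26, adjusted p = 0.116) and Ifitm3 (-1.41 ± 0.52, adjusted p = 0.195), did not pass. The replicates in DMEM lay apart, with mean log2 CPM over this list of 2.74 and 4.41 against 1.39 and 1.75 in NSC medium, and Isg15 at 27.8 and 594 against 7.83 and 19.1 CPM. Of the 22 NF-kB target genes edgeR passed 0, DESeq2 8 and limma 0, with 11 at an unadjusted p under 0.05 in edgeR and 11 passing adjusted over the list alone. The NF-kB target list had a median log2 difference of -1.48, adjusted p = 1.08e-07 (adjusted p = 0.346 with an estimated correlation). Among the 12 pluripotency genes edgeR passed 0, DESeq2 3 and limma 0, with 6 at an unadjusted p under 0.05 in edgeR and 4 passing adjusted over the list alone. The pluripotency list had a median log2 difference of 1.5 (1.36 with bounds), adjusted p = 0.00278 (adjusted p = 0.346 with an estimated correlation). Its mean log2 CPM here was at most 1.243.

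The count and its direction depended on single libraries and on the filter. It was 154 (44 higher and 110 lower) without replicate 1 and 91 (39 and 52) without replicate 2 of the neurons in DMEM, and 47 and 43 without those in NSC medium. Of the 52 transcripts these kept 29, 24, 12 and 19. It was 1011 (473 and 538) without the filter. With at least 50 counts required it was 90 (68 and 22), by the DESeq2 test 813 (418 and 395) and by limma voom 61. With these 4 libraries alone edgeR called 0, and 1359 had an unadjusted p under 0.05.

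Transduced astrocytes in NSC medium were compared with untransduced astrocytes in serum to see what the virus and the new medium changed together in glia. Astrocyte and microglia genes fell, and ribosomal, matrix and RAS-MAPK genes rose. Gfap, the classic astrocyte filament gene, went from 2379 and 2049 CPM to 2.12 and 5.6 CPM. In edgeR, 4350 of 13132 transcripts tested changed, 2095 higher and 2255 lower. Of the 21 astrocyte genes, 17 fell (17 adjusted over the list alone), with a median log2 change of -4.80 (-4.60 with bounds), adjusted p = 3.43e-10 (adjusted p = 0.346 with an estimated correlation). Gfap fell by 9.11 ± 1.23 (adjusted p = 0.000607), with the water channel Aqp4 (-11.29 ± 1.07, adjusted p = 0.00014), Ntsr2 (at least 123-fold) and Gpr37l1 (-9.30 ± 0.69). Among the 24 microglia and macrophage genes, 23 fell (24 adjusted over the list alone), with a median log2 change of -8.29 (-7.95 with bounds), adjusted p = 1.32e-16 (adjusted p = 0.346 with an estimated correlation). C1qb (at least 577-fold, adjusted p = 0.000216), C1qc (at least 359-fold, adjusted p = 0.000353) and Fcer1g (at least 291-fold) fell most, beside the macrophage genes Fcrls (at least 3319.6-fold), P2ry13 (at least 403-fold) and Ms4a7 (at least 318-fold). Slco1a4 (at least 3709-fold, adjusted p = 0.000922) and Ttr (at least 25513-fold, adjusted p = 0.00243) fell as well, although Ttr stood at 6932 and 82.0 CPM in the Astrocyte replicates.

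Among the 23 RAS-MAPK output genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 2.53, adjusted p = 1.1e-06 (adjusted p = 0.346 with an estimated correlation). Areg (at least 525-fold, adjusted p = 0.000463), Ereg (7.99 ± 1.05), Hmga2 (9.34 ± 1.24) and Cdkn2a (5.0 ± 0.39, adjusted p = 7.76e-05) rose as in neurons. The largest rises were the keratin gene Krt20 (at least 10742-fold, adjusted p = 0.000968), the calcium-channel subunit Cacng3 (at least 5268-fold, adjusted p = 0.00072), the potassium channel Kcnq1 (at least 2973-fold, adjusted p = 2.4e-06) and the cation channel Trpa1 (at least 583-fold, adjusted p = 0.00191), with Serpinb11 (at least 282-fold) and Tmprss11d (at least 244-fold). Kcnq1 had 0 counts in both Astrocyte libraries and 371 and 434 CPM in the transduced ones. Among 35 cytosolic ribosomal protein genes, 30 rose (32 adjusted over the list alone), with a median log2 change of 1.73, adjusted p = 1.72e-11 (adjusted p = 0.346 with an estimated correlation). Rps19 (2.67 ± 0.42) is an example. Among 33 matrix and adhesion genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 1.69, adjusted p = 3.26e-05 (adjusted p = 0.631 with an estimated correlation). The protease gene Mmp10 (1958-fold, 95% interval 351 to 77379) and the laminin genes Lama4 (6.65 ± 0.56) and Lamb1 (6.01 ± 0.75) rose. Among the 22 NF-kB target genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 change of 2.82, adjusted p = 0.000219 (adjusted p = 0.491 with an estimated correlation). Il6 (at least 25.5-fold, adjusted p = 0.00148), Cxcl1 (132-fold, 95% interval 44.7 to 642, adjusted p = 0.00114) and Ccl2 (5.48 ± 0.75) rose. Among 27 mesenchymal glioma genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 1.32, adjusted p = 0.00478 (adjusted p = 0.632 with an estimated correlation). Plau (5.24 ± 0.84) and Tnc (4.68 ± 0.43) rose. Igfbp3 rose by 3.85 (adjusted p = 0.0158), from 4041 and 5199.7 CPM to 67296 and 65481 CPM, 5.34% and 5.89% of all counts.

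Among 28 unfolded protein and amino acid stress genes, 11 rose (12 adjusted over the list alone), with a median log2 change of 0.92, adjusted p = 0.000144 (adjusted p = 0.346 with an estimated correlation). The cystine carrier Slc7a11 (4.61 ± 0.65, adjusted p = 0.000744) and Asns (4.07 ± 0.64) rose. Of the 24 glycolysis and hypoxia genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone), with a median log2 change of 1.41, adjusted p = 0.000371 (adjusted p = 0.561 with an estimated correlation). Car9 (5.46 ± 0.87) and the lactate carrier Slc16a3 (at least 14.1-fold) rose. Of the 19 immediate early genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone), with a median log2 change of 2.06, adjusted p = 0.0208 (adjusted p = 0.501 with an estimated correlation). Egr3 (at least 47.8-fold) rose and Ccn2 (-6.29 ± 0.80) fell. Of the 14 neuronal structure genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with a median log2 change of -0.44, adjusted p = 0.754 (adjusted p = 0.964 with an estimated correlation). The test and the mean pointed up there while the median was below 0, and Nefl (10.10 ± 1.55), Nefm (7.68 ± 1.00) and Gap43 (4.50 ± 0.56) rose. Of the 31 neural stem and progenitor genes, 2 rose and 14 fell (2 and 15 adjusted over the list alone), with a median log2 change of -0.79, adjusted p = 0.00352 (adjusted p = 0.567 with an estimated correlation). Fabp7 (-7.75 ± 0.94) and Sox1 (-7.26 ± 0.59) fell. Among 10 endothelial and blood genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), with a median log2 change of 1.62, adjusted p = 0.156 (adjusted p = 0.501 with an estimated correlation). Esam (8.90 ± 1.08) rose.

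Leaving out 1 of these 4 libraries lowered the count, to 2069 and 2205 without Astrocyte replicates 1 and 2, and to 2394 and 2733 without those of the transduced astrocytes.

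**Figure D3:**
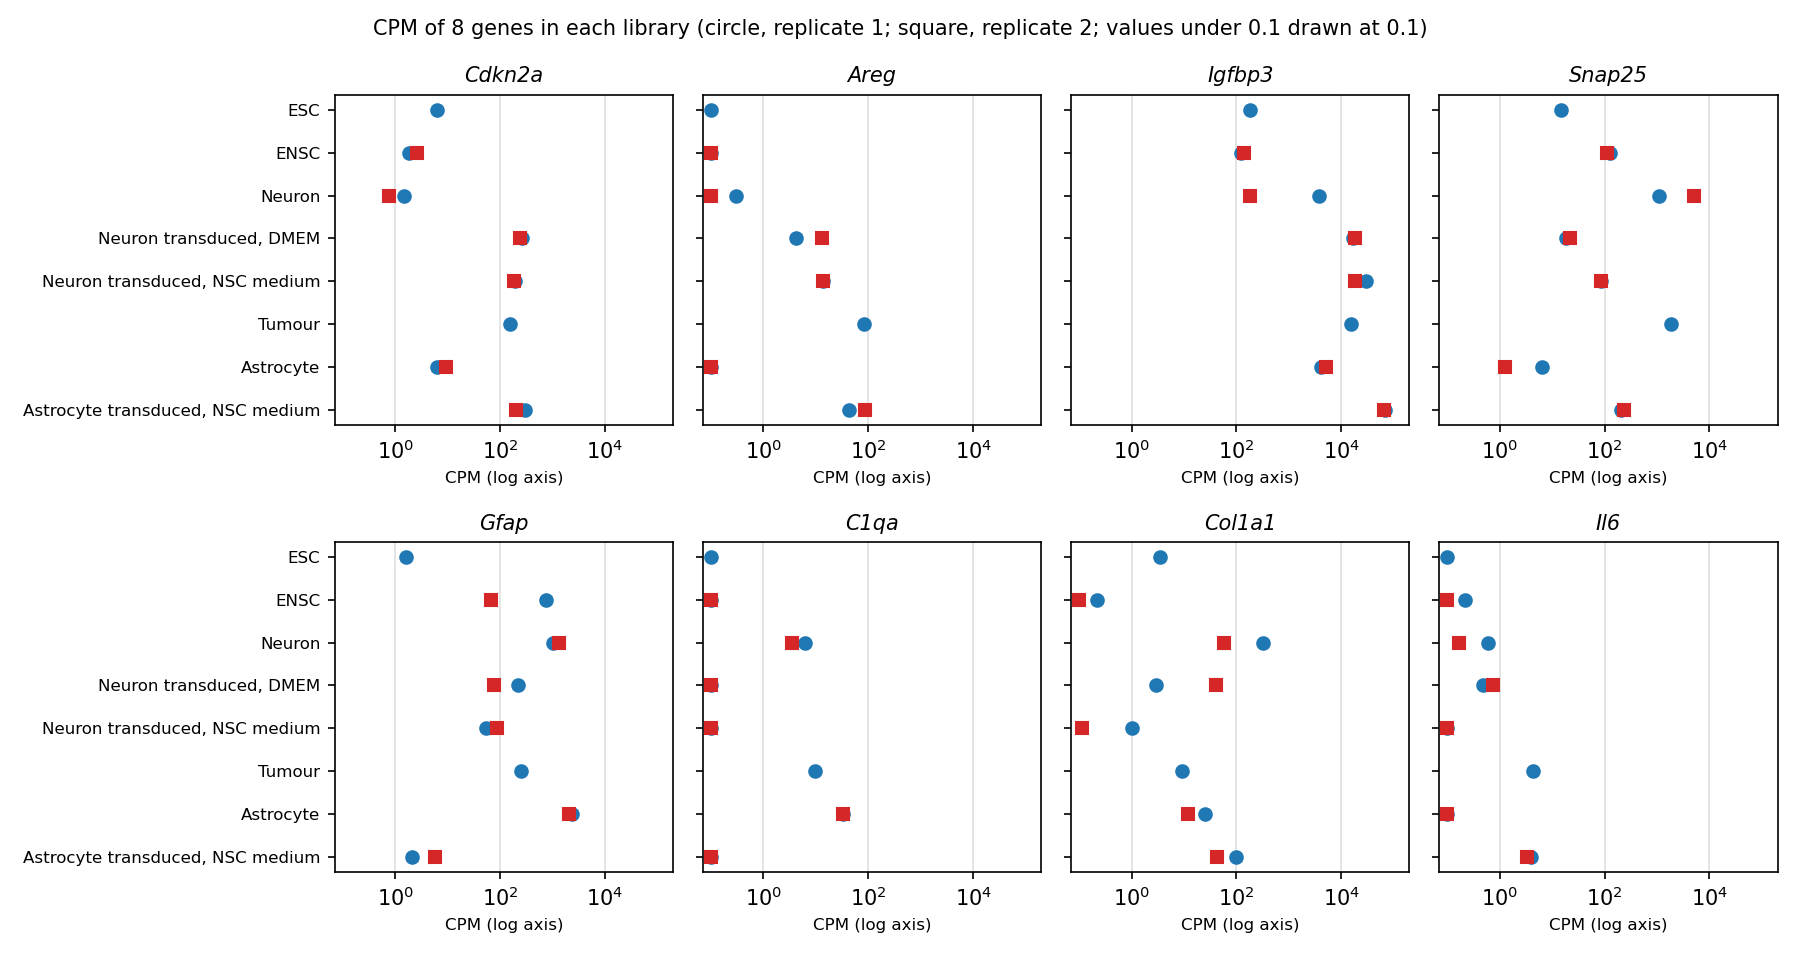
CPM of 8 genes in each library on a log axis, circles for replicate 1 and squares for replicate 2, with values under 0.1 CPM drawn at 0.1. Cdkn2a and Areg are higher in each transduced or tumour library than in any untransduced culture, and Igfbp3 is highest in transduced astrocytes at 67296 and 65481 CPM.

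The changes of neurons and of astrocytes in NSC medium were then set against each other, as the change in neurons minus the change in astrocytes. The matrix, synapse and NF-kB target lists had the lower change in neurons, and the astrocyte and microglia lists the higher, each with a part of its genes passing. Collagen gene Col1a1 went from 316 and 58.0 to 1.03 and 0.114 CPM in neurons and from 25.4 and 12.1 to 98.6 and 42.9 CPM in astrocytes. In edgeR 1062 transcripts differed, 549 with a higher and 513 with a lower change in neurons. Of the 33 matrix and adhesion genes, 17 had a lower change in neurons (23 adjusted over the list alone), with a median log2 difference of -3.73, adjusted p = 5.4e-10 (adjusted p = 0.46 with an estimated correlation). Col1a2 differed by -10.29 ± 2.04. Out of 22 NF-kB target genes, 6 had a lower change in neurons (1 and 9 adjusted over the list alone), with a median log2 difference of -1.93, adjusted p = 3.05e-06 (adjusted p = 0.399 with an estimated correlation). Il6 reached 3.93 and 3.35 CPM in transduced astrocytes. Among the 23 synapse genes, 1 had a higher and 7 a lower change in neurons (1 and 9 adjusted over the list alone), with a median log2 difference of -3.27, adjusted p = 5.6e-07 (adjusted p = 0.473 with an estimated correlation). Snap25 fell in neurons from 1087 and 5035 to 86.0 and 85.9 CPM and rose in astrocytes from 6.5 and 1.27 to 207 and 231 CPM.

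Among the 21 astrocyte genes, 10 had a higher change in neurons (11 adjusted over the list alone), with a median log2 difference of 2.57, adjusted p = 1.69e-06 (adjusted p = 0.422 with an estimated correlation). Aqp4 fell in both, from 2692 and 2067 to 69.5 and 134 CPM in neurons and from 1347 and 1317 to 0.604 and 0.467 CPM in astrocytes. Among the 31 neural stem and progenitor genes, 9 had a higher and 3 a lower change in neurons (11 and 3 adjusted over the list alone), with a median log2 difference of 0.59, adjusted p = 0.00212 (adjusted p = 0.534 with an estimated correlation). Fabp7 differed by 6.98 ± 1.09. Out of 24 microglia and macrophage genes, 3 had a higher change in neurons (6 adjusted over the list alone), with a median log2 difference of 3.12, adjusted p = 7.33e-09 (adjusted p = 0.423 with an estimated correlation). Cx3cr1 started at 9.65 and 4.65 CPM in Neuron and 676 and 506 CPM in Astrocyte, and the list as a whole also started higher in Astrocyte. Of the 35 cytosolic ribosomal protein genes, 1 had a lower change in neurons (1 adjusted over the list alone), with a median log2 difference of -1.12, adjusted p = 1.64e-07 (adjusted p = 0.346 with an estimated correlation). Rpl8 differed by -1.85 ± 0.42. Slc7a11 differed by -5.52 ± 0.84.

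The count was 593 and 526 without replicates 1 and 2 of the transduced neurons, 328 and 295 without those of Astrocyte, and 352 and 360 without those of the transduced astrocytes. Without the filter it was 2074, and by the DESeq2 test 1781.

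Untransduced neurons were compared with untransduced astrocytes. Neuronal genes were far higher in the neuron cultures, and microglia genes lower. The astrocyte list had mean log2 CPM of 7.40 and 7.07 in Neuron, near the 7.57 and 7.44 in Astrocyte. In edgeR, 2163 transcripts differed, 1284 higher and 879 lower. Out of 23 synapse genes, 19 were higher (19 adjusted over the list alone), with a median log2 difference of 5.46 (5.45 with bounds), adjusted p = 4.63e-12 (adjusted p = 0.346 with an estimated correlation). Slc17a6 (at least 348-fold, adjusted p = 0.00356) and Snap25 (9.59 ± 0.98) were higher. Among the 14 neuronal structure genes, 10 were higher and 1 lower (10 and 1 adjusted over the list alone), with a median log2 difference of 3.27, adjusted p = 5.18e-06 (adjusted p = 0.363 with an estimated correlation). Ina (7.38 ± 0.91) and Nefl (6.72 ± 1.45) were higher. So were Neurod1 (at least 890.3-fold, adjusted p = 0.0046) and Adcyap1 (at least 526-fold, adjusted p = 0.00671). Of 24 microglia and macrophage genes, 9 were lower (20 adjusted over the list alone), with a median log2 difference of -2.44, adjusted p = 2.79e-11 (adjusted p = 0.376 with an estimated correlation). Cx3cr1 (-6.37 ± 0.59, adjusted p = 0.00108) and Csf1r (-5.21 ± 0.57) were lower, with Npvf (-7.77 ± 1.78) and Aldh1a1 (-5.40 ± 0.98). Of the 21 oligodendrocyte lineage genes, 7 were higher (9 adjusted over the list alone), with a median log2 difference of 2.45, adjusted p = 7.64e-05 (adjusted p = 0.483 with an estimated correlation). The count was 851 without Neuron replicate 2, 258 and 90 without Astrocyte replicates 1 and 2, and 144 with these 4 libraries alone.

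After transduction and NSC medium, neurons were compared with astrocytes. Astrocyte, neural stem and proneural gene lists were higher in the transduced neuron cultures, and matrix, mesenchymal and NF-kB lists lower. In edgeR, 2019 of 13132 transcripts tested differed, 1192 higher and 827 lower. Out of 21 astrocyte genes, 11 were higher (12 adjusted over the list alone), with a median log2 difference of 2.89 (2.49 with bounds), adjusted p = 4.36e-07 (adjusted p = 0.399 with an estimated correlation). Aqp4 (7.58 ± 0.96, adjusted p = 0.00132) and Gfap (4.16 ± 1.00) were higher. Out of 31 neural stem and progenitor genes, 12 were higher and 4 lower (14 and 5 adjusted over the list alone), with a median log2 difference of 1.44, adjusted p = 0.000184 (adjusted p = 0.468 with an estimated correlation). Fabp7 (7.25 ± 0.92) and Ptprz1 (6.63 ± 0.67) were higher. Among 26 proneural glioma genes, 7 were higher (11 and 1 adjusted over the list alone), with a median log2 difference of 1.21 (1.11 with bounds), adjusted p = 0.000562 (adjusted p = 0.346 with an estimated correlation). Olig2 (4.60 ± 0.52, adjusted p = 0.000625) and Sox8 (4.90 ± 0.80) were higher. Of the 27 mesenchymal glioma genes, 7 were lower (13 adjusted over the list alone), with a median log2 difference of -1.29, adjusted p = 2.64e-05 (adjusted p = 0.472 with an estimated correlation). Among the 33 matrix and adhesion genes, 17 were lower (22 adjusted over the list alone), with a median log2 difference of -2.52, adjusted p = 5.59e-11 (adjusted p = 0.435 with an estimated correlation). Col1a2 (-7.70 ± 1.64, adjusted p = 0.0126) was lower, with Kcnq1 (-10.62 ± 0.41), Dkk2 (-7.95 ± 0.94) and Esam (-7.50 ± 0.99). Of 22 NF-kB target genes, 9 were lower (13 adjusted over the list alone), with a median log2 difference of -1.84, adjusted p = 4.07e-08 (adjusted p = 0.346 with an estimated correlation). Kcnma1 (492-fold, 95% interval 88.0 to 19488), Ccl22 (462-fold, 95% interval 82.5 to 18281) and Ppp2r2c (413-fold, 95% interval 73.8 to 16359) were higher. Vrk1 was high in replicate 2 only, at 0.516 and 567 CPM in the neuron cultures. The count was 1287 and 889 without replicates 1 and 2 of the transduced neurons, and 683 and 486 without those of the transduced astrocytes.

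The ENSC libraries were compared with neurons to define the reference state. Their labels conflict, a title of ENSC standing beside a cell type of embryonic stem cells. Neural progenitor genes were higher, and matrix and cell-division genes lower, than in Neuron. In edgeR, 2420 of 13132 transcripts tested differed, 783 higher and 1637 lower. Of 31 neural stem and progenitor genes, 13 were higher and 1 lower (16 and 1 adjusted over the list alone), with a median log2 difference of 1.24, adjusted p = 1.16e-06 (adjusted p = 0.363 with an estimated correlation). The Notch ligands Dll3 (5.09 ± 0.37, adjusted p = 0.000105) and Dll1 (3.72 ± 0.52, adjusted p = 0.00181) and the transcription factor Sox3 (3.13 ± 0.63) were higher. Among 25 sterol synthesis genes, 9 were higher (15 adjusted over the list alone), with a median log2 difference of 1.12, adjusted p = 0.000197 (adjusted p = 0.534 with an estimated correlation). Among the 32 G2 and M phase genes, 12 were lower (23 adjusted over the list alone), with a median log2 difference of -1.89, adjusted p = 2.51e-07 (adjusted p = 0.592 with an estimated correlation). Top2a (-2.43 ± 0.56) was lower. Out of 33 matrix and adhesion genes, 21 were lower (24 adjusted over the list alone), with a median log2 difference of -4.55 (-4.08 with bounds), adjusted p = 4.63e-12 (adjusted p = 0.409 with an estimated correlation). Col1a1 (1393-fold, 95% interval 476 to 6758) was lower. Lists of other cell types moved with it, the meningeal and mural list by a median of -6.18 (-5.27 with bounds, adjusted p = 4.92e-11, and 0.346 with an estimated correlation) and the microglia list by -5.15 (-5.07 with bounds, 6.81e-14 and 0.346). Out of 12 pluripotency genes, 4 were lower (4 adjusted over the list alone), with a median log2 difference of -0.60, adjusted p = 0.191 (adjusted p = 0.613 with an estimated correlation). Klf2 (at least 7.16-fold) and Klf4 (-2.67 ± 0.76) were lower. Other large differences were Fndc3c1 (455-fold, 95% interval 126 to 3763) and Six3os1 (4.45 ± 0.61), higher, and Stab1 (at least 433-fold, adjusted p = 0.000932) and Cxcl12 (at least 323-fold), lower. The count was 785 and 330 without ENSC replicates 1 and 2, and 784 with these 4 libraries alone.

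Transduced neurons in NSC medium were compared with ENSC. They were higher in cell-division, RAS-MAPK and mesenchymal genes and lower in neural stem genes. In edgeR, 2831 of 13132 transcripts tested differed, 1621 higher and 1210 lower. Among 31 neural stem and progenitor genes, 4 were higher and 18 lower (5 and 19 adjusted over the list alone), with a median log2 difference of -1.98, adjusted p = 3.05e-06 (adjusted p = 0.394 with an estimated correlation). Dll1 (-6.36 ± 0.61, adjusted p = 0.000314) and Hes5 (-4.23 ± 0.96) were lower. Out of 32 G2 and M phase genes, 24 were higher (29 adjusted over the list alone), with a median log2 difference of 2.30, adjusted p = 4.92e-11 (adjusted p = 0.473 with an estimated correlation). Cdk1 (3.77 ± 0.69) was higher. Out of 23 RAS-MAPK output genes, 18 were higher and 1 lower (19 and 1 adjusted over the list alone), with a median log2 difference of 4.45, adjusted p = 2.28e-10 (adjusted p = 0.345 with an estimated correlation). Hmga2 (9.47 ± 1.25, adjusted p = 0.00102) was higher. Among the 27 mesenchymal glioma genes, 19 were higher (21 adjusted over the list alone), with a median log2 difference of 2.83, adjusted p = 4.09e-10 (adjusted p = 0.346 with an estimated correlation). Fam110c (at least 1769.6-fold, adjusted p = 0.00829) and Angpt2 (11.45 ± 0.74) were far higher, and Prkcq (490.5-fold, 95% interval 168 to 2381) and Slc30a10 (-7.87 ± 0.90, adjusted p = 0.000552) far lower. The count was 1217 and 821 without ENSC replicates 1 and 2, and 1784 and 1667 without those of the transduced neurons.

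Transduced astrocytes were compared with ENSC in the same way. Matrix and NF-kB target genes were higher, and neural stem genes lower. In edgeR, 5570 of 13132 transcripts tested differed, 2787 higher and 2783 lower. Of 33 matrix and adhesion genes, 29 were higher (29 adjusted over the list alone), with a median log2 difference of 5.45, adjusted p = 6.08e-13 (adjusted p = 0.399 with an estimated correlation). Mmp3 (at least 288-fold, adjusted p = 0.00117) was higher, and the meningeal and mural list moved with it, by a median of 4.03 (3.87 with bounds, adjusted p = 0.000541, and 0.534 with an estimated correlation). Of the 31 neural stem and progenitor genes, 4 were higher and 23 lower (4 and 24 adjusted over the list alone), with a median log2 difference of -2.77, adjusted p = 1.29e-07 (adjusted p = 0.346 with an estimated correlation). Bcan (-10.10 ± 1.39) and Rfx4 (at least 45.6-fold) were lower. Among 22 NF-kB target genes, 17 were higher (17 adjusted over the list alone), with a median log2 difference of 5.31 (4.59 with bounds), adjusted p = 2.38e-08 (adjusted p = 0.346 with an estimated correlation). Saa3 (at least 215-fold) was higher. Fam110c (at least 9269-fold, adjusted p = 0.0018) and Adgrl4 (at least 1299.7-fold) were far higher, and Slc6a11 (at least 8969.5-fold, adjusted p = 0.00171) and Kcna2 (at least 1053-fold) far lower. The count was 3659 and 3388 without ENSC replicates 1 and 2.

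The single ESC library was compared with ENSC, taking ESC to vary as the replicated groups do. Pluripotency and cell-division genes were higher in ESC and neural stem genes higher in ENSC. In edgeR, 5210 of 13132 transcripts tested differed, 2743 higher and 2467 lower. The low-count filter kept 12 of 28 pluripotency genes, without Nanog, and 12 were higher (12 adjusted over the list alone). Their median log2 difference was 9.73 (9.34 with bounds), adjusted p = 2.66e-09 (adjusted p = 0.345 with an estimated correlation). Lin28a stood at 4763 CPM in ESC and at 3.14 and 3.68 CPM in ENSC, and L1td1 (10.47 ± 0.65, adjusted p = 2.9e-05) was higher too. Of the 27 S-phase genes, 27 were higher (27 adjusted over the list alone), with a median log2 difference of 4.54, adjusted p = 7.03e-13 (adjusted p = 0.422 with an estimated correlation). Of 32 G2 and M phase genes, 31 were higher (31 adjusted over the list alone), with a median log2 difference of 4.82, adjusted p = 1.55e-13 (adjusted p = 0.422 with an estimated correlation). Among the 31 neural stem and progenitor genes, 2 were higher and 25 lower (2 and 26 adjusted over the list alone), with a median log2 difference of -4.90 (-4.82 with bounds), adjusted p = 1.37e-09 (adjusted p = 0.346 with an estimated correlation). Hes5 (at least 144-fold, adjusted p = 0.00336) and Fabp7 (-8.72 ± 1.35) were lower. Nup62cl (at least 181-fold) and D1Pas1 (at least 335-fold) were far higher, and Six3 (at least 321-fold) and Plxnb3 (at least 211-fold) far lower. Trp53 was higher in ESC, by 3.56 ± 0.64 (adjusted p = 0.00177). With these 3 libraries alone 7902 transcripts passed.

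The single tumour library was compared with untransduced neurons, the cells that a SynapsinI-Cre mouse targets. Ribosomal and RAS-MAPK genes were higher, and neural stem genes lower. In edgeR, 1908 of 13132 transcripts tested differed, 1024 higher and 884 lower. Among the 35 cytosolic ribosomal protein genes, 19 were higher (30 adjusted over the list alone), with a median log2 difference of 1.48, adjusted p = 3.24e-12 (adjusted p = 0.346 with an estimated correlation). Rplp2 (4.11 ± 0.97, adjusted p = 0.0238) and Rps20 (3.30 ± 0.40) were higher. Of 23 RAS-MAPK output genes, 12 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median log2 difference of 2.13, adjusted p = 6.29e-07 (adjusted p = 0.346 with an estimated correlation). Areg (596-fold, 95% interval 203 to 2899, adjusted p = 0.00496) and Hmga2 (5.75 ± 1.11) were higher, as were Cdkn2a (7.11 ± 0.47, adjusted p = 0.0002), Calcb (at least 582-fold) and the collagenase Mmp1a (at least 241-fold, adjusted p = 0.0274). Out of 27 mesenchymal glioma genes, 9 were higher (10 adjusted over the list alone), with a median log2 difference of 1.89, adjusted p = 3.54e-05 (adjusted p = 0.473 with an estimated correlation). Plaur (5.50 ± 0.98) and Lgals1 (4.31 ± 0.65) are examples. Out of 31 neural stem and progenitor genes, 13 were lower (1 and 18 adjusted over the list alone), with a median log2 difference of -2.06, adjusted p = 3.12e-07 (adjusted p = 0.346 with an estimated correlation). Ncan (-5.30 ± 0.85, adjusted p = 0.0078) and Fabp7 (-5.19 ± 1.13) were lower. Dlx1 (-7.16 ± 0.69, adjusted p = 0.00236), Pnoc (173-fold, 95% interval 30.8 to 6833) and Dpysl5 (-6.81 ± 1.07), genes of interneurons and young neurons, were lower too. Of 23 synapse genes edgeR passed 0, DESeq2 6 and limma 0, with 10 at an unadjusted p under 0.05 in edgeR and 0 passing adjusted over the list alone. The synapse list had a median log2 difference of -1.74 (-1.73 with bounds), adjusted p = 0.00784 (adjusted p = 0.729 with an estimated correlation). Among 24 microglia and macrophage genes edgeR passed 0, DESeq2 2 and limma 1, with 3 at an unadjusted p under 0.05 in edgeR and 0 passing adjusted over the list alone. The microglia and macrophage list had a median log2 difference of 0.73, adjusted p = 0.019 (adjusted p = 0.791 with an estimated correlation).

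The count was 1020 without Neuron replicate 2, 3207 without the filter and 73 with these 3 libraries alone. The DESeq2 test called 2954, of which 42.4% were higher in the tumour, against 53.7% of the edgeR calls.

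The tumour was also compared with transduced neurons in NSC medium, the same virus in a brain and in culture. Microglia and macrophage genes were far higher in the tumour. In edgeR, 1385 of 13132 transcripts tested differed, 712 higher and 673 lower. Of the 24 microglia and macrophage genes, 17 were higher (21 adjusted over the list alone), with a median log2 difference of 5.89 (5.65 with bounds), adjusted p = 1.9e-16 (adjusted p = 0.346 with an estimated correlation). C1qa (at least 66.1-fold, adjusted p = 0.0074), C1qc (1004-fold, 95% interval 179 to 39746, adjusted p = 0.00617), Ly86 (558-fold, 95% interval 190.2 to 2714) and the scavenger receptor Msr1 (536-fold, 95% interval 95.2 to 21278, adjusted p = 0.0122) were higher. Of the 22 NF-kB target genes, 7 were higher (8 adjusted over the list alone), with a median log2 difference of 1.72, adjusted p = 0.000357 (adjusted p = 0.501 with an estimated correlation). Il6 (86.4-fold, 95% interval 14.5 to 3512) was higher. Of the 22 meningeal fibroblast and mural genes, 4 were higher (11 and 2 adjusted over the list alone), with a median log2 difference of 3.19 (2.88 with bounds), adjusted p = 0.00367 (adjusted p = 0.613 with an estimated correlation). Col3a1 (6.85 ± 1.36) was higher. Of 31 neural stem and progenitor genes, 12 were lower (1 and 15 adjusted over the list alone), with a median log2 difference of -1.76, adjusted p = 3.46e-07 (adjusted p = 0.346 with an estimated correlation). Ncan (-6.67 ± 0.91, adjusted p = 0.00714) and Olig2 (-4.95 ± 0.71) were lower, with Sorcs1 (-5.82 ± 1.32). Prg4 (9.83 ± 1.20, adjusted p = 0.00617) was also far higher. The count was 227 and 726 without replicates 1 and 2 of the transduced neurons, 2389 without the filter and 2259 by the DESeq2 test.

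Positions between starting cells and ENSC were computed over all transcripts tested, 0 at the starting cells and 1 at ENSC. Transduced neurons lay at 0.344 ± 0.058 (SD, n = 2) in NSC medium and 0.305 ± 0.11 (SD, n = 2) in DMEM. Transduced astrocytes lay at 0.322 ± 0.027 (SD, n = 2) from Astrocyte, and the tumour at -0.031 from Neuron. Over transcripts that differed between ENSC and the starting cells these were 0.43 for neurons in NSC medium, 0.36 for astrocytes and 0.082 for the tumour, the last with its sign turned. The measure was not specific to ENSC. On the neuron axis ESC lay at 0.498, untransduced Astrocyte libraries at 0.160 and 0.201 and transduced astrocytes at 0.277 and 0.252. On the astrocyte axis the Neuron libraries lay at 0.352 and 0.525.

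**Figure D4:**
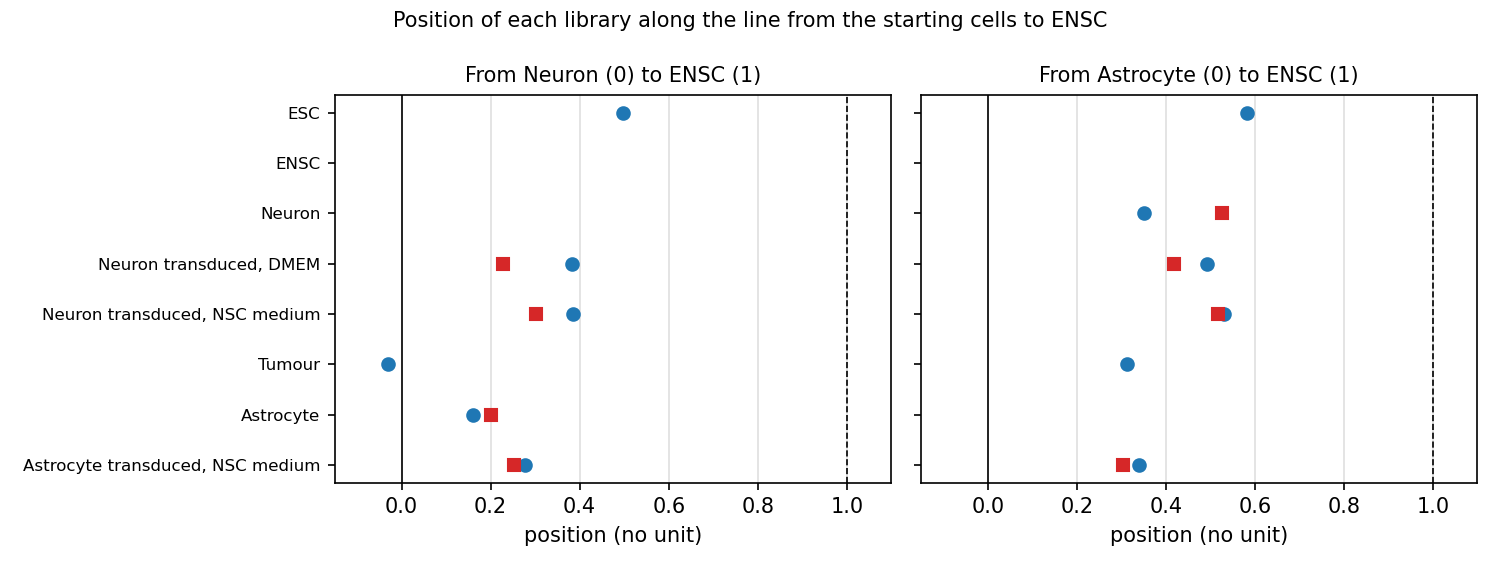
Position of each library on the line from Neuron (0) to ENSC (1) and from Astrocyte (0) to ENSC (1). Transduced neurons in NSC medium average 0.344 and transduced astrocytes 0.322, while untransduced astrocytes stand at 0.160 and 0.201 on the neuron line.

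Changes were compared between comparisons across genes, which are not independent replicates. Changes from Neuron in DMEM and in NSC medium correlated with r = 0.825. Both subtract the same Neuron libraries, and simulated data without shared changes gave r = 0.497. The covariance was 1.688 against 0.167 simulated, and with a different Neuron library subtracted from each r was 0.609. They shared 524 higher and 803 lower transcripts, and 3 were opposite. Independent lists would share 91.1 and 125, a value that leaves out the Neuron libraries both subtract. The tumour and the transduced neurons in NSC medium, both against Neuron, correlated with r = 0.528, against 0.397 simulated and 0.352 with different Neuron libraries. Their covariance was 1.139 against 0.166 simulated, and 271 higher and 244 lower were shared, against 61.9 and 73.7 for independent lists, which again leaves out the common libraries. For the tumour and transduced neurons in DMEM r was 0.46, against 0.4 simulated and 0.298 with different Neuron libraries, and the covariance was 1.025 against 0.167. The changes of neurons and astrocytes in NSC medium share no control and correlated with r = 0.481. They had 429 higher and 528 lower transcripts in common, against 127 and 188 by independence, and 76 opposite. Astrocyte and tumour changes correlated with r = 0.443, and 0.477 where at least 50 counts were required.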

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

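The results in this part stood out because the change with transduction and NSC medium differed between neurons and astrocytes, by the interaction term of edgeR for genes and of camera for lists. The difference of changes and its tests were planned. Among the tests of explanations, the ratio of total counts and all 3 tests on the matrix genes were chosen after the result was seen. With 2 libraries in each group, no group was tested for a library far from the others.

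The term passed for 1062 transcripts. Lists with a lower change in neurons were neuronal structure (adjusted p = 0.0143, and 0.613 with an estimated correlation), synapse (5.6e-07 and 0.473), NF-kB targets (3.05e-06 and 0.399), matrix and adhesion (5.4e-10 and 0.46), meningeal fibroblast and mural (0.000132 and 0.495), ribosomal proteins (1.64e-07 and 0.346), unfolded protein and amino acid stress (0.00182 and 0.346) and immediate early genes (0.00947 and 0.47). Astrocyte (1.69e-06 and 0.422), neural stem (0.00212 and 0.534) and microglia and macrophage genes (7.33e-09 and 0.423) had a higher one.

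Genes with a higher change in neurons were Npvf (13.80 ± 2.59, adjusted p = 0.0128, at 24.9 and 2.17 CPM in transduced neurons and 0 and 0.31 in transduced astrocytes), Kcnj10 (8.62 ± 1.13, 0.00276), Cx3cr1 (7.54 ± 0.82, 0.00124), Gpr37l1 (7.31 ± 0.79, 0.00124), Fabp7 (6.98 ± 1.09, 0.00561), Aqp4 (6.74 ± 1.13, 0.00782), P2ry12 (6.34 ± 1.52, 0.0316) and Map2 (4.01 ± 0.73, 0.0114). Lower ones were Snap25 (-10.94 ± 1.16, adjusted p = 0.00124), Col1a2 (-10.29 ± 2.04, 0.0151), Col1a1 (-10.13 ± 1.83, 0.0108), Nefl (-7.21 ± 1.75, 0.0334), Slc7a11 (-5.52 ± 0.84, 0.00494), Asns (-4.31 ± 0.84, 0.0145), Nr4a1 (-4.19 ± 1.05, 0.0379) and Rpl8 (-1.85 ± 0.42, 0.0257). Where a group had 3 counts or fewer, CPM stand for the fold. Fcrls (adjusted p = 0.0322) went from 684 and 290 to 0 CPM in both astrocyte libraries and from 23.2 and 3.29 to 0.17 and 0.80 in neurons. Aldh1a1 (0.0443) went from 26.6 and 40.1 to 0 CPM in astrocytes. Kcnq1 (0.000129), Krt20 (0.0241) and Cacng3 (0.00815) were at 0 CPM in Astrocyte and reached 371 and 434, 1438 and 1517, and 387 and 908 in the transduced ones. Slc17a6 (0.00653) went from 9.55 and 81.6 to 0.09 and 0.11 CPM in neurons, and Cxcl1 (0.00514) from 0.16 and 0.11 to 12.5 and 21.2 in astrocytes. Rfx4 (0.0477), Il6 (0.00859) and Egr3 (0.0486) passed too.

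Microglia and macrophage genes fell with transduction in neurons and astrocytes. Fewer counts in the transduced libraries do not account for it, as these held 1.28 times the mean total of the untransduced ones. Another set of 76 microglia genes, written before it was tested and sharing no gene with the 24 lists, had 56 measured members, and in the transduced groups at least 85.7% of them lay 2-fold or more below the starting cells, where 20.8% to 26.1% of all transcripts did. In the tumour 94.6% lay 2-fold or more above transduced neurons in NSC medium, against 21.0% of all. Its abundant member Lcp1 went from 761 and 1022 CPM in Astrocyte to 3.63 and 1.79, and Arhgdib from 1002 and 251 in Neuron to 20.4 and 36.5 in NSC medium, with 1286 in the tumour, although it kept 358 and 212 CPM in transduced astrocytes. Microglia or macrophages that the transduced cultures lack and the tumour holds are a candidate explanation. A change within the brain cells stays untested, as the design joins virus, medium and time in culture.

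Matrix and adhesion genes had a lower change in neurons than in astrocytes, with a median difference of changes of -3.73. In NSC medium against Neuron 5 of 33 rose and 13 fell, with a median of -0.82 (adjusted p = 0.0466, and 0.859 with an estimated correlation), and in astrocytes 14 rose and 1 fell. Mean log2 CPM over the list was 6.64 and 4.91 in Neuron and 4.46 in both libraries in NSC medium, so the fall in neurons is small against Neuron replicate 2. Fibroblast-like cells lost from Neuron or 1 Neuron library are not the whole cause, as the list rose in astrocytes. Both stay open for the fall in neurons, as the tests include that rise. Transduced neurons lay below transduced astrocytes by a median of -2.52 (quartiles -3.76 and -1.12). The -3.73 became -2.48 without Neuron replicate 1 and -4.52 without replicate 2. Outgrowth of meningeal or mural cells in the transduced astrocyte cultures stays open, by a quartile rule set last. Their 19 markers outside the matrix list changed by a median of -1.49 with 7 falls and 4 rises, and their quartiles (-2.75 and 1.93) span the 1.69 of the matrix list. With DESeq2 size factors, run first and replaced by the outgrowth test, the list median was -3.80. A difference between neuron- and astrocyte-derived cells remains a hypothesis. Culture medium and library preparation were not tested.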

How the results depend on the processing

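Summing counts by symbol was chosen after the data were examined, and the other alternatives were planned. Depth limits genes at a few counts, whose folds have wide counting intervals. With 2 libraries a group the simulated test recovered 1 of 50 changes of 2-fold and 25 of 4-fold. In the difference of changes it was 1 and 5. Where a cause is not named below, the cause was not tested.

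All 13 counts of transcripts stayed within 1.5 times with DESeq2 size factors, limma voom and sums by symbol. DESeq2 size factors moved the share of higher calls from 42.0% to 34.3% in NSC medium against Neuron, from 50.2% to 43.5% in DMEM and from 32.4% to 23.4% for ENSC against Neuron. With voom ENSC against Neuron had 41.3%, Neuron against Astrocyte fell from 59.4% to 50% and the transduced pair from 59.0% to 50.5%. Of the 1039 results for single genes (each gene counted once per comparison and naming), 912 kept their direction and side of the threshold with voom, 1019 with DESeq2 size factors, 1022 by the DESeq2 test (of 1034 that it covers), 1028 without the filter, 1033 summed by symbol and 670 with the compared groups alone, and none turned its sign.

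Without the filter counts were 3104 in NSC medium against Neuron, 1011 for NSC medium against DMEM, 2074 for the difference of changes, 3207 for the tumour against Neuron and 2389 against transduced neurons. By the DESeq2 test the last 4 were 813, 1781, 2954 and 2259. With at least 50 counts 90 differed between the media. The compared groups alone gave 0 in DMEM (2957 at an unadjusted p under 0.05, and 4961 in the fit of all groups). They gave 0 between the media, 352 in NSC medium, 144 for Neuron against Astrocyte, and 784 for ENSC and 73 for the tumour against Neuron. Counts rose to 6198 in astrocytes and 7902 for ESC against ENSC. Replicates agreed least in Neuron and DMEM, where the shared spread may be too small.

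Leaving out 1 library at a time gave 386 (without NSC medium replicate 1) to 2326 (without Neuron 1) in NSC medium against Neuron, 1083 (without DMEM 2) to 3257 (without DMEM 1) in DMEM, 43 (without NSC medium 2) to 154 (without DMEM 1) between the media, and 2069 (without Astrocyte 1) to 2733 (without transduced 2) in astrocytes. It gave 295 (without Astrocyte 2) to 1493 (without Neuron 1) for the difference of changes, 90 (without Astrocyte 2) to 2555 (without Neuron 1) for Neuron against Astrocyte, 486 (without astrocyte 2) to 1287 (without neuron 1) for the transduced pair, and 330 (without ENSC 2) to 2175 (without Neuron 1) for ENSC against Neuron. Against ENSC the range was 821 (without ENSC 2) to 1784 for transduced neurons and 3388 (without ENSC 2) to 3973 for astrocytes. The tumour had 1020 (without Neuron 2) to 2384 (without Neuron 1) against Neuron, and 227 and 726 against transduced neurons. Leaving out 1 library also moved the share of higher calls by over 10 points, from 42.0% to 27.1% (without Neuron 2) and 54.4% (without NSC medium 1) in NSC medium, from 50.2% to 36.6% (without Neuron 2) in DMEM, from 71.2% to between 28.6% and 87.2% between the media, from 48.2% to 35.9% and 34.7% (without Astrocyte 1 or 2) in astrocytes and from 51.7% to 64.4% (without Astrocyte 2) in the difference of changes. It moved from 59.4% to 74.4% (without Neuron 2) for Neuron against Astrocyte, and without NSC medium 1 from 59.0% to 70.3% for the transduced pair, from 57.3% to 70.5% against ENSC and from 51.4% to 30.8% for the tumour against it. A group left with 1 library is assumed to vary like the others. Over all such fits, single genes kept their side of the threshold in 2525 results and lost it in 1423, gained it in 2 and turned in 6.

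Positions on transcripts that differed between ENSC and the starting cells were 0.43 for neurons in NSC medium, 0.36 for astrocytes and 0.082 for the tumour, whose sign turned. Splitting the Neuron libraries between comparisons lowered r to 0.609 for the media, 0.352 for NSC medium and tumour and 0.298 for DMEM and tumour, and at least 50 counts raised r of astrocyte and tumour changes to 0.477. Of the 167 list calls, camera with an estimated correlation kept 0 of 312 tests, fry kept 113, at least 50 counts 158 and DESeq2 size factors 165, none with the direction turned. Trp53, which passed in none of these, ran from -1.14 to 0.35 (without Neuron 1) in NSC medium, from -0.01 (without Neuron 2) to 1.48 in the difference of changes, from -0.64 to 0.26 (without astrocyte 1, and 0.16 without neuron 2) in the transduced pair, and from -0.074 (without Neuron 2) to 1.42 for ENSC against Neuron. For Gpr17 in genes changed in transduced astrocytes in NSC medium against astrocytes the value ran from -10.25 to 0 without Astrocyte 1, the only library of these with its counts.

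Replicate numbers are shared without a stated link, and deviations of same-numbered libraries correlated at -0.185 to 0.173 over 15 pairs of groups. With the replicate number as a replicate block NSC medium against DMEM gave 141 transcripts, the other 9 counts between replicated groups stayed within 1.5 times, and 126 of 127 list calls were kept. Of single genes 752 results kept their side of the threshold, 56 lost it and 1 gained it.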

Other observations

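The genes and tests below were chosen after their values were seen, apart from the tests on shared reads and on chromosomal neighbours, which were written before. Igfbp3 was the most abundant transcript in 6 of the 7 transduced or tumour libraries, with 1.61% to 5.89% of the counts. Tested genes at 20 CPM or more and over 20-fold above all other libraries were sought by group. Genes low outside a single library, like Nanog of ESC, were not tested. The tumour held Ccl6 (787 CPM), Prg4 (190), Lyve1 (118) and Ly6a (60). Transduced astrocytes held Kcnq1 (371 and 434), Esam (104 and 179) and Trpa1 (29.2 and 108). Dll3 was the gene of ENSC, Cx3cr1 of Astrocyte and Gng4 (117 and 190) of Neuron, ESC had 42, and transduced neurons 0. Vrk1 stood at 567 CPM in replicate 2 of transduced neurons in NSC medium, 291 in the tumour and at most 1.82 elsewhere.

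Transcripts of the 37 genes lower in DMEM than in NSC medium lay below the 12 other libraries in both DMEM libraries for 25. Actb stood at 306 and 389 CPM in DMEM against 1499 and 1864 in NSC medium. If DMEM lowered them in any culture, Astrocyte libraries, also kept in DMEM, would lie near 0 between DMEM (0) and NSC medium (1). Their median was 0.628 with quartiles of 0.150 and 0.847, and since the rule that the lower quartile must clear 0.25 was set after the values were seen, this stays open. Reads shared with pseudogenes or paralogs do not explain most of them, as 30.6% (11 of 36) share at least 10% of their 24-base words with another gene, against 12.3% of 12409 symbols tested, but a part may be affected.

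Xist and the summed Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty differed within groups. In 3 groups, transduced neurons in DMEM, Astrocyte and transduced astrocytes, 1 library had under 3 CPM of the Y-linked transcripts and the other more than 20 CPM with less Xist, so the libraries of a group may have drawn on animals of different sex. Astrocyte had 339 and 0.528 CPM of Xist and 0.329 and 147 CPM Y-linked, and transduced astrocytes 215 and 0.467 against 0.906 and 108. Neuron replicate 1 (278 CPM Xist, 52.1 CPM Y-linked), replicate 2 in DMEM (120 and 65.1) and both libraries in NSC medium (163 and 76.4, 201 and 39.2) showed both, so the contrast in DMEM (189 and 0.684 in replicate 1) is not one of single sexes.

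A change of the surrounding chromosomal region was tested for Kcnq1 and Vrk1 over the 10 nearest genes tested. Around Kcnq1 the median change in astrocytes was 1.09, above 97.2% of 12409 such windows. That met the bound written before, but the neighbours ran from -4.97 to 3.76 (quartiles -0.42 and 2.25) with 6 of 10 above 0, so a rule on the lower quartile was added for both genes after the values were seen and the question stays open. Around Vrk1 the median difference was -0.19, which argues against such a change.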
